A study of Arabidopsis thaliana with 6 samples.

How the data were processed

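Leaves of Arabidopsis thaliana were sampled from plants held at 100 ppm CO2 for 24 h or kept at 400 ppm. Each of the 3 replicates per condition pooled 4 to 5 plants, per the labels, so the replicates are separate pools, and nothing in the labels says that they were grown at separate times. Biotin-labelled cRNA was made from 5 µg total RNA for Affymetrix arrays, per the labels. The authors deposited log2 expression values made with GCRMA, per the submitters' processing notes, which gave no version. GCRMA corrects background by probe sequence, normalizes between arrays and summarizes probes, which draws weakly hybridised probe sets to a common floor and makes the arrays' distributions alike. The log base is not stated in the sources used here and was read from the values, which ran from about 2.6 to 14.2 on each array. Probe sets carry a locus name, 1 per locus, and the version of this grouping and the genome build are not given in the sources used here. No coordinates are therefore printed. Names came from a RefSeq gene table of assembly TAIR10.1, in which 21231 of 21430 loci were found, and a better known name is printed where the table's symbol is an older one. Among the 21430 probe sets, 221 share all 6 values with another, and such genes are not named.

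Groups and replicate numbers were taken from the labels. Probe sets at log2 4 or above on at least 3 of the 6 arrays were kept, which left 16210 and set aside 5220. Low CO2 was compared with ambient CO2 in limma 3.58.1 in R 4.3.3, with lmFit and eBayes without trend or robust settings, no replicate term, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none was used for single values. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 24 lists with at least 5 tested members each. They comprised 19 gene lists (photorespiration, Calvin-Benson cycle, photosystems and light harvesting, carbonic anhydrases and C4-cycle enzymes, sugar starvation, starch and sugar storage, flavonoids and anthocyanins, oxidative stress, heat shock, abscisic acid with cold and drought, jasmonate, salicylate and pathogen defence, aliphatic glucosinolates, circadian clock, nitrogen assimilation, senescence and chlorophyll breakdown, autophagy, cell wall expansion and growth, touch and rapid stress) and 5 marker lists (guard cells and stomatal lineage, epidermis and trichomes, vascular tissue, dividing cells, roots). Of 453 list entries, 17 were kept under the table's symbol, 0 were dropped and 396 were tested. Some genes stand in more than 1 list.

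The lists, tests, thresholds, naming rule and other settings to try were fixed before the data were examined. The rule named the 12 largest rises and 12 largest falls with adjusted p under 0.05 and no overlap of the groups, which 0 genes met, the 4 members of each list with the smallest p, and GLDP1, SHM1, HPR1, GLYK, PLGG1, CAT2, ASN1, CA1 and CCA1. Its first part was applied afterwards to the fit without low CO2 replicate 1, and this choice was made after seeing the data. The lack of overlap was still judged with replicate 1 included. List members singled out as exceptions, TCH2 and EXPA1, were also chosen after their values were seen. The other settings were no filter, a floor of log2 5, eBayes with trend and robust, quantile normalization, centring of each array on its median, the replicate number as a block, array weights, Holm adjustment, each array left out in turn, and for lists an estimated correlation and the fry test. A threshold of 0.10 and the count of probe sets without overlap when low CO2 replicate 1 is left out were added after seeing the data.

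The fit was tested on simulated data with the real spread of 16210 probe sets and 50 changed probe sets per size, drawn at random. With all 6 arrays, limma recovered 66%, 86%, 96% and 100% of changes of log2 1, 2, 3 and 4, with 6 false calls. Without low CO2 replicate 1 it recovered 68%, 90%, 98% and 100%, with 7 false calls. A simulated list of 20 genes shifted by log2 1 was called in both, and 0 of 24 lists left alone were. These lists were random draws of independent probe sets, so the check says nothing of false calls where list genes move together. After the data were seen, 50 draws of unchanged values with the spread of each probe set, independent between probe sets, and 50 with the fitted effects in low CO2 replicates 2 and 3 alone, gave the values that shared ambient arrays produce. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.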

Results

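Gene expression was measured in leaves of Arabidopsis thaliana that had grown for 6 weeks in soil under short days. Plants were then moved to air with 100 ppm CO2 for 24 h or stayed at 400 ppm, a comparison the series places under photorespiratory stress, the condition in which Rubisco fixes more oxygen and the photorespiratory cycle has to recycle more of its product. There were 3 arrays of low CO2 plants and 3 of ambient CO2 plants, each from leaf material pooled over 4 to 5 plants. Of 21430 probe sets, each named for 1 locus, 16210 reached log2 4 on at least 3 of the 6 arrays and were tested. The arrays' medians lay between log2 6.07 and 6.11. The number of arrays limits the precision of every value below.

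Leaves kept in low CO2 had higher levels of genes of oxidative stress, sugar starvation, abscisic acid, cold and drought responses, rapid stress responses, senescence, salicylate defence, autophagy and the circadian clock than leaves in ambient air. Genes of aliphatic glucosinolate synthesis, cell wall expansion and dividing cells were lower. These 11 lists of 24 passed limma's camera test with a preset inter-gene correlation, 8 of them higher and 3 lower, and 0 of the 24 passed with an estimated correlation. Genes of the photorespiratory cycle, the Calvin-Benson cycle and the photosystems did not pass as lists. In single genes, limma called 0 probe sets higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.0719 shared by 16 probe sets, among them those of CBP60G, WRKY53 and EXPA16. At an unadjusted p under 0.05 there were 4236 probe sets, where chance gives 810.5. The 3 low CO2 values lay above all 3 ambient values for 2365 probe sets and below them for 2316, together 28.9% of those tested, where chance gives 10%.

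Low CO2 replicate 1 stood apart from the other low CO2 arrays. Across the tested probe sets, which are not independent replicates, its values correlated at r = 0.986, 0.980 and 0.982 with the 3 ambient arrays but at 0.962 and 0.947 with low CO2 replicates 2 and 3, which correlated with each other at 0.992. On the first principal component, with 75.7% of the variance, replicate 1 lay at -13.2, replicates 2 and 3 at 46.4 and 60.9, and the ambient arrays at -22.4, -33.5 and -38.2. Leaving that array out, 1 of 6 omissions fixed before the data were examined, gave 2722 probe sets higher and 3001 lower by limma, of which 925 and 571 changed at least 2-fold, and 7559 at an unadjusted p under 0.05. Counts of list members called without this array are to be read against these rises and falls among all 16210 probe sets. The array is singled out because it stood apart, and leaving it out narrows the spread of the low CO2 group. Limma p values without it are therefore likely too small, and the counts too large. Leaving out any other single array gave 0 calls, with 2145 and 2251 probe sets at an unadjusted p under 0.05 without low CO2 replicates 2 and 3, and 3972, 2539 and 2034 without ambient replicates 1, 2 and 3. Of the 5723 probe sets called without low CO2 replicate 1, that array differed from the ambient mean in the same direction for 4214, or 73.6%. Both differences use the same ambient arrays, and simulated data with no effect in replicate 1 gave 54.4% (53.4% to 55.4% over 50 draws), so part of the share may come from those arrays. It remains in its group in every value below unless the text says otherwise.

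**Figure D1:**
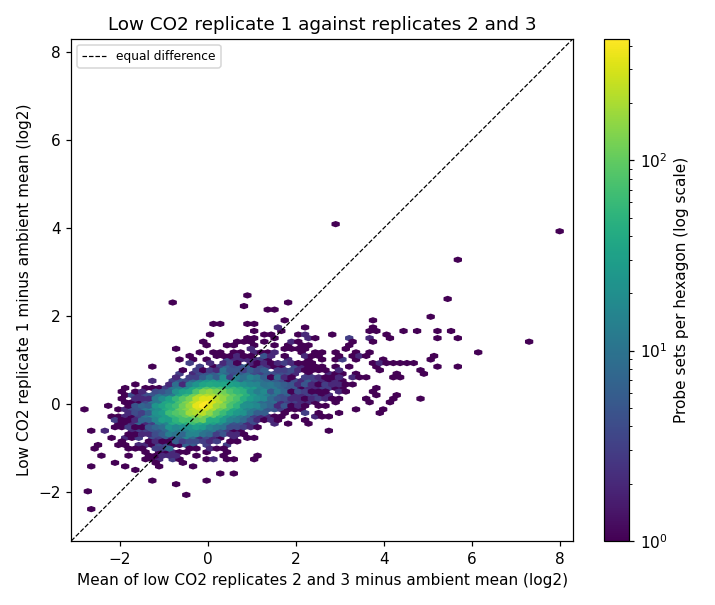
Log2 difference from the ambient mean of each tested probe set, for low CO2 replicate 1 (vertical axis) against the mean of low CO2 replicates 2 and 3 (horizontal axis); colour gives the number of probe sets per hexagon on a log scale and the dashed line marks equal differences. Over the 16210 probe sets the slope of replicate 1 on the mean of the other pair was 0.233, with r = 0.492 and a covariance of 0.104 across probe sets; both axes use the same ambient arrays, and simulated data gave 0.401, 0.317 and 0.0105 with no effect on any array and at most 0.0270, 0.0916 and 0.0127 over 50 draws with effects in replicates 2 and 3 alone.

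Oxidative stress genes were the list with the smallest p. Of 21 tested, 19 were higher in low CO2, with a median log2 difference of 1.01 (camera adjusted p = 1.83e-07, and adjusted p = 0.497 with an estimated correlation). By limma 0 members passed over all genes, 15 rose when adjusted over the list alone, and 16 rose over all genes without low CO2 replicate 1. The median was 0.38 in low CO2 replicate 1, 1.19 in replicate 2 and 1.83 in replicate 3. UGT74E2, a glucosyltransferase gene known to respond to hydrogen peroxide, stood at log2 10.75 ± 2.37 (SD, n = 3) in low CO2 and 4.09 ± 0.17 in ambient air, a 101-fold difference whose ambient side lies near the lower end of the array's range. The difference of UGT74E2 was 256-fold without low CO2 replicate 1 and 55.2-fold without low CO2 replicate 3. AOX1A, the alternative oxidase of mitochondria, stood at 11.91 ± 1.25 against 9.0 ± 0.25, and its 7.53-fold difference became 12.4-fold without low CO2 replicate 1 (limma adjusted p = 1.23e-04). The zinc finger gene ZAT10 differed by 2.66 on the log2 scale (SE 0.45), and NDB2, an external NAD(P)H dehydrogenase of mitochondria, by 0.91 (SE 0.17). All 4 rose when adjusted over the list alone.

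Genes induced by sugar starvation came next. The median log2 difference over 25 genes was 0.96, with 23 higher (camera adjusted p = 5.13e-06, and adjusted p = 0.507 with an estimated correlation). This list split the low CO2 arrays, with medians of 0.07 in replicate 1, 1.31 in replicate 2 and 1.69 in replicate 3. The median of ambient replicate 1 lay 0.56 above the other ambient arrays, further than low CO2 replicate 1 above the ambient mean. Over all genes 0 members passed limma, adjusted over the list alone 3 rose, and without low CO2 replicate 1 22 rose over all genes. DIN9 (log2 difference 1.1, SE 0.20) and SEN1 (3.14, SE 0.66), both named for their induction in darkness or senescence, were among the 3. The proline dehydrogenase gene ProDH1 stood 2.07 higher (SE 0.64). Leaving out replicate 1 moved SEN1 to 3.88 and ProDH1 to 2.86. ASN1, an asparagine synthetase induced in the dark, had a mean of log2 8.39 ± 2.05 in low CO2 and 5.81 ± 0.37 in ambient air, and its values overlapped between the groups because replicate 1 lay only 0.21 above the ambient mean. Without that array ASN1 rose by 3.77 on the log2 scale (limma adjusted p = 1.45e-04), and without low CO2 replicate 3 it differed by 1.97. The 12 autophagy genes followed the same split, with medians of -0.20, 0.87 and 1.16 in low CO2 replicates 1, 2 and 3 (camera adjusted p = 7.93e-04, and adjusted p = 0.585 with an estimated correlation). On ambient replicate 1 their median lay 0.19 above the other ambient arrays. All 12 had a higher mean in low CO2, 0 passed limma over all genes or adjusted over the list alone, and 12 rose over all genes without low CO2 replicate 1. ATG5, needed for conjugating ATG8, differed by 1.00 (SE 0.30), ATG8H by 1.18 (SE 0.39), the cargo receptor NBR1 by 0.68 (SE 0.24) and ATG8G by 0.72 (SE 0.29).

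Genes of abscisic acid, cold and drought responses were higher, with a median log2 difference of 0.81 over 24 genes, 21 of them higher (camera adjusted p = 1.72e-05, and adjusted p = 0.507 with an estimated correlation). Adjusted over the list alone 11 rose, over all genes 0, and without low CO2 replicate 1 17 rose over all genes. RAB18, a dehydrin, stood at 9.47 ± 0.49 in low CO2 and 7.45 ± 0.16 in ambient air, a 4.06-fold difference. LEA4-5, another late embryogenesis abundant protein gene, differed by 0.81 (SE 0.13), the abscisic acid phosphatase gene ABI1 by 0.85 (SE 0.17) and the transcription factor gene DREB2A by 2.33 (SE 0.57), and all 4 rose when adjusted over the list alone. DREB2A differed by 2.97 without low CO2 replicate 1 and by 1.72 without low CO2 replicate 3. The list's median was 0.09 in low CO2 replicate 1, against 0.82 and 1.09 in replicates 2 and 3. On ambient replicate 2 it lay 0.34 above the other ambient arrays. Among 14 genes of touch and rapid stress responses the median was 1.11 (camera adjusted p = 1.72e-05, and adjusted p = 0.497 with an estimated correlation). Of these 0 passed over all genes, while 11 rose and 1, the calmodulin-like gene TCH2, fell when adjusted over the list alone. Over all genes 9 rose and 1 fell without low CO2 replicate 1. Besides ZAT10, which belongs to both lists, WRKY33 differed by 1.84 (SE 0.37), the zinc finger gene SZF1 by 1.68 (SE 0.40) and WRKY40 by 1.64 (SE 0.41). The medians on low CO2 replicates 1, 2 and 3 were 0.56, 1.69 and 1.26.

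**Figure D2:**
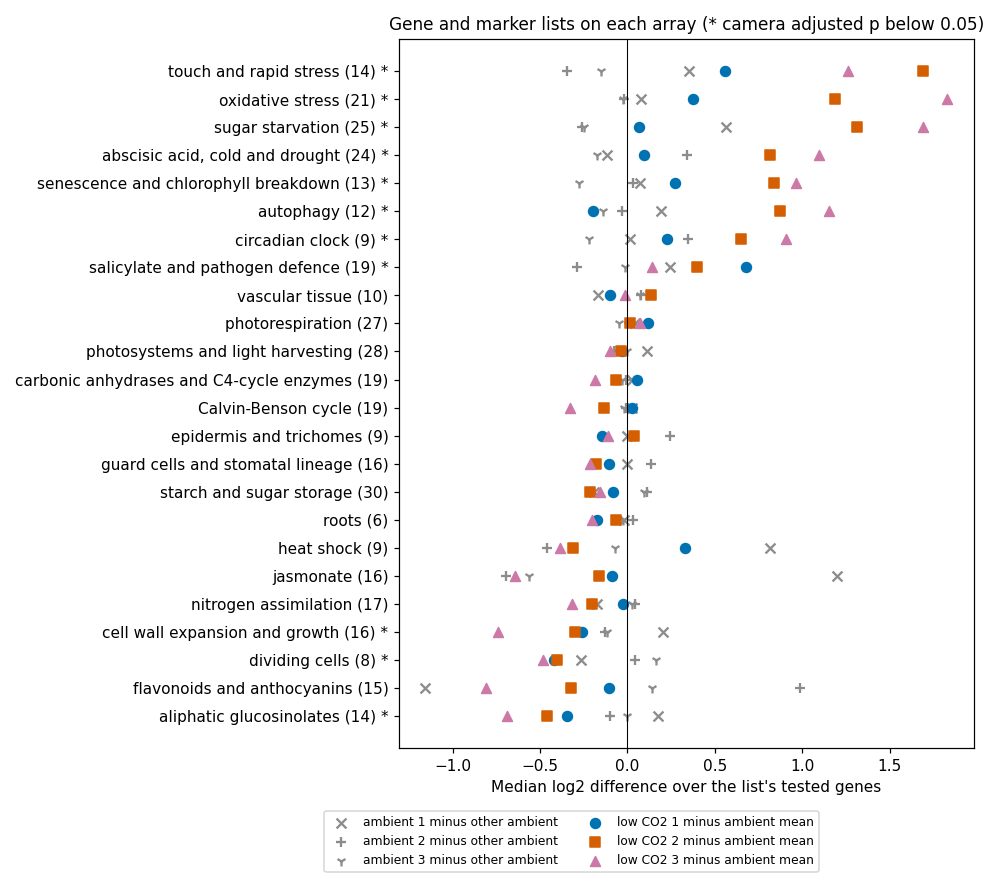
Median log2 difference over the tested genes of each list (number in brackets) on each array; filled symbols are low CO2 replicates against the ambient mean, grey symbols are each ambient array against the mean of the other ambient arrays, and a star marks camera adjusted p below 0.05 with the preset correlation. For sugar starvation the low CO2 medians were 0.07, 1.31 and 1.69, while for salicylate and pathogen defence they were 0.68, 0.40 and 0.14.

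Senescence and chlorophyll breakdown genes had a median log2 difference of 0.69 over 13 genes (camera adjusted p = 1.91e-04, and adjusted p = 0.497 with an estimated correlation), and the medians on low CO2 replicates 1, 2 and 3 were 0.27, 0.84 and 0.96. Over all genes 0 passed limma, adjusted over the list alone 8 rose, and 9 rose over all genes without low CO2 replicate 1. WRKY53, a regulator of early senescence, was highest in low CO2 replicate 1, at 2.14 above the ambient mean, and differed by 1.75 (SE 0.20) over the group. The transcription factor gene NAP differed by 1.76 (SE 0.43), ORE1 by 2.13 (SE 0.58) and ACD2, red chlorophyll catabolite reductase, by 0.42 (SE 0.12), and these 4 rose when adjusted over the list alone. Genes of salicylate and pathogen defence had a median of 0.40 over 19 genes (camera adjusted p = 5.72e-04, and adjusted p = 0.507 with an estimated correlation). Here low CO2 replicate 1 had the highest median, 0.68, against 0.40 and 0.14 in replicates 2 and 3, and without it the camera adjusted p was 0.0617, in a range from 2.33e-06 over the 6 omissions. Adjusted over the list alone 4 rose, over all genes 0, and without replicate 1 5 rose and 1 fell over all genes. The 4 were CBP60G (1.19, SE 0.14) and WRKY46 (0.81, SE 0.19), both transcription regulators of salicylate signalling, the defence regulator PAD4 (0.72, SE 0.12) and the salicylate receptor gene NPR1 (0.49, SE 0.13).

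Clock genes were higher as a list, with a median log2 difference of 0.61 over 9 genes (camera adjusted p = 0.00368, and adjusted p = 0.497 with an estimated correlation). The time of day at which either group was harvested is not given in the sources used here. Adjusted over the list alone 3 rose, over all genes 0, and without low CO2 replicate 1 6 rose over all genes. The 3 were the morning-phased RVE1 (2.6, SE 0.63), the evening gene TOC1 (0.76, SE 0.22) and PRR7 (0.61, SE 0.18). RVE1 lay 1.04 above the ambient mean on replicate 1 and differed by 3.39 without it. CCA1, a morning gene, differed by 0.55 (SE 0.19) with overlapping values. The list's medians on low CO2 replicates 1, 2 and 3 were 0.23, 0.65 and 0.91. On ambient replicate 2 the median lay 0.35 above the other ambient arrays.

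Aliphatic glucosinolate genes were lower, with 12 of 14 below the ambient mean and a median log2 difference of -0.53 (camera adjusted p = 9.02e-05, and adjusted p = 0.497 with an estimated correlation). Low CO2 replicates 1, 2 and 3 had medians of -0.34, -0.46 and -0.69. Adjusted over the list alone 9 fell, over all genes 0, and without low CO2 replicate 1 9 fell over all genes. The first count included MYB29, a transcription factor of the pathway (log2 difference -1.05, SE 0.15), SOT17, a sulfotransferase of the last step of core synthesis (7.98 ± 0.31 in low CO2 against 9.17 ± 0.16), the side chain oxygenase gene FMO GS-OX1 (-0.80, SE 0.16) and the chloroplast transporter gene BAT5 (-0.56, SE 0.13). Among 16 genes of cell wall expansion and growth the median was -0.34 (camera adjusted p = 0.0181, and adjusted p = 0.507 with an estimated correlation). Without ambient replicate 1 the camera adjusted p of this list was 0.213, in a range from 0.00302 over the 6 omissions. Over all genes 0 passed limma, and adjusted over the list alone 6 fell and 1, the expansin gene EXPA1, rose. Leaving out low CO2 replicate 1, 1 rose and 7 fell over all genes. The xyloglucan endotransglucosylase genes XTH4 (-1.0, SE 0.15), XTH9 (-0.74, SE 0.15) and XTH8 (-1.38, SE 0.35) and the growth regulator PRE1 (-1.07, SE 0.24) were among those that fell when adjusted over the list alone. The medians were -0.26, -0.30 and -0.74 on low CO2 replicates 1, 2 and 3.

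Of the cell type markers, those of dividing cells were lower in all 8 members tested, with a median log2 difference of -0.43 (camera adjusted p = 0.00206, and adjusted p = 0.497 with an estimated correlation). Adjusted over the list alone 4 fell, over all genes 0, and without low CO2 replicate 1 4 fell over all genes. PCNA1, the sliding clamp of DNA replication, stood at 7.37 ± 0.43 against 8.28 ± 0.20, and the cytokinesis syntaxin gene KNOLLE differed by -0.68 (SE 0.18). The medians on low CO2 replicates 1, 2 and 3 were -0.42, -0.41 and -0.49, but members differed in both directions, with PCNA1 at -0.43 on replicate 1 and -1.15 without it and KNOLLE at -1.05 and -0.50. Markers of guard cells and the stomatal lineage went both ways (median -0.13 over 16, camera adjusted p = 0.293), with 2 up and 5 down when adjusted over the list alone, 0 over all genes, and 2 up and 3 down over all genes without low CO2 replicate 1. The receptor-like gene TMM differed by 0.47 and the kinase gene OST1 by 0.45, while the protease gene SDD1 differed by -0.79 and the potassium channel gene KAT1 by -1.04. Markers of epidermis and trichomes (median -0.12 over 9, camera adjusted p = 0.853), vascular tissue (0.02 over 10, camera adjusted p = 0.853) and roots (-0.14 over 6, camera adjusted p = 0.293) had 0 members past the threshold over all genes and 0 adjusted over the list alone. Without low CO2 replicate 1, 1 epidermal marker rose, 1 root marker fell and 0 vascular markers passed over all genes, with medians of -0.08, -0.13 and 0.08 for epidermis, roots and vascular tissue. The vascular median turned to -0.01 after quantile normalization or centring of the arrays on their medians.

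Photorespiratory genes on the array, the process the series title names, differed little and in both directions. Of 30 listed, 27 had a probe set, while PGLP1, GOX1 and GOX2 had none and were not measured. The median log2 difference over 27 genes was 0.02 (camera adjusted p = 0.293), and -0.01 after centring of the arrays on their medians. In fry's test of movement in 1 direction, upward here, the adjusted p was 0.0986, the same as for the clock and senescence lists that camera called. By limma 0 passed over all genes, and 3 rose and 1 fell when adjusted over the list alone. GLDP1 and GLDP2, the P proteins of glycine decarboxylase, stood at 13.20 ± 0.13 against 12.72 ± 0.08 and at 12.25 ± 0.13 against 11.75 ± 0.13. AOAT2, a glutamate:glyoxylate aminotransferase, differed by 0.45 (SE 0.12), and the chloroplast 2-oxoglutarate/malate transporter gene DiT1 by -0.78 (SE 0.21). CAT2, the leaf peroxisomal catalase, differed by 0.33 (SE 0.11) and the hydroxypyruvate reductase gene HPR1 by 0.29 (SE 0.12), neither past the threshold. The serine hydroxymethyltransferase gene SHM1 (-0.02, SE 0.12), the glycerate kinase gene GLYK (-0.09, SE 0.10) and the glycolate/glycerate transporter gene PLGG1 (-0.04, SE 0.12) lay within 1 SE of no difference, and SHM1 and PLGG1 changed sign after quantile normalization. Without low CO2 replicate 1, 4 members rose and 6 fell over all genes, with a list median of 0.05. That fit called 2722 of all 16210 probe sets higher and 3001 lower.

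**Figure D3:**
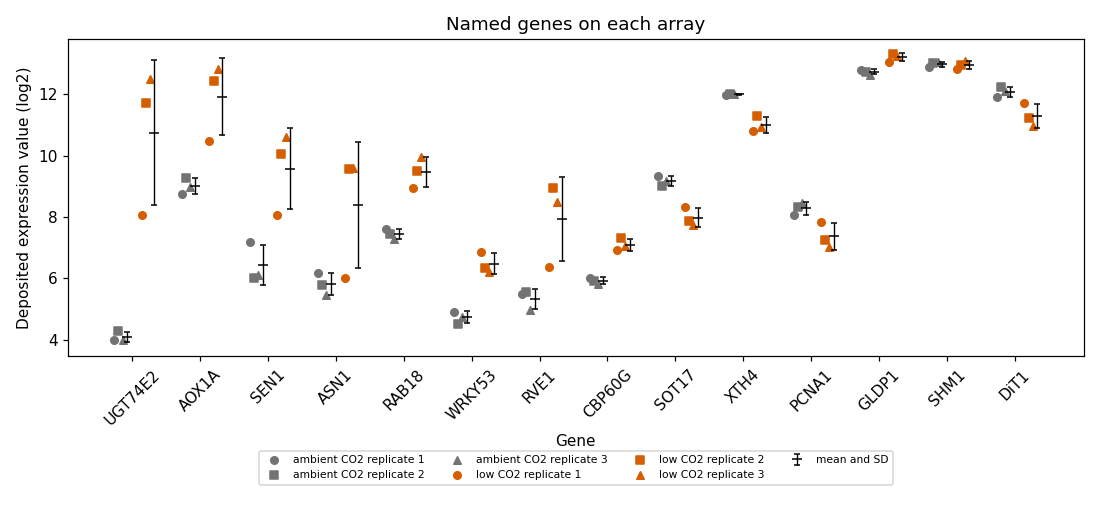
Deposited log2 values of 14 named genes on each array, with ambient arrays in grey and low CO2 arrays in orange; circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD of 3 arrays. UGT74E2 had a mean of 10.75 in low CO2 and 4.09 in ambient air, while the photorespiratory genes GLDP1, at 13.20 against 12.72, and SHM1, at 12.95 against 12.97, lay close together.

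Other lists of primary metabolism also did not pass as lists. Their counts without low CO2 replicate 1 stand beside 2722 probe sets higher and 3001 lower among all 16210 tested. Calvin-Benson genes had a median log2 difference of -0.11 over 19 (camera adjusted p = 0.640), where CP12-2, a small regulator of the cycle, rose by 0.92 (SE 0.18) when adjusted over the list alone and 0 passed over all genes. Their medians on low CO2 replicates 1, 2 and 3 were 0.02, -0.13 and -0.33, and the median without replicate 1 was -0.27. Of the Calvin-Benson genes 2 rose and 4 fell over all genes without low CO2 replicate 1. The list held 23 genes, but the Rubisco small subunit genes RBCS1A, RBCS1B, RBCS2B and RBCS3B had no probe set. The 28 genes of photosystems and light harvesting had a median of -0.06 (camera adjusted p = 0.457), or -0.00440 after quantile normalization (camera adjusted p = 0.998), with 0 past the threshold over all genes, adjusted over the list alone, or without low CO2 replicate 1. Their 4 smallest p values belonged to PSBQA, PSAH2, LHCB5 and LHCB6, which differed by -0.21, -0.20, -0.14 and -0.15. Carbonic anhydrases and C4-cycle enzymes had a median of -0.08 over 19 (camera adjusted p = 0.702) and 0 members past the threshold over all genes or adjusted over the list alone. Of these 3 rose and 5 fell over all genes without low CO2 replicate 1, where the median was -0.14. The main leaf carbonic anhydrase gene CA1 differed by 0.08 (SE 0.10) and the pyruvate orthophosphate dikinase gene PPDK by 0.71 (SE 0.16). Starch and sugar storage genes had a median of -0.14 over 30 (camera adjusted p = 0.599). The starch synthase gene SS4 (0.65, SE 0.14) and the beta-amylase gene BAM1 (0.88, SE 0.19) rose when adjusted over the list alone, 0 over all genes, and without low CO2 replicate 1 3 rose and 2 fell over all genes, with a list median of -0.21. In nitrogen assimilation (median -0.21 over 17, camera adjusted p = 0.599) 2 rose and 2 fell when adjusted over the list alone and 0 passed over all genes. With low CO2 replicate 1 left out, 4 rose and 7 fell over all genes. Those higher when adjusted over the list alone were the ammonium transporter gene AMT1;1 (0.93) and the cytosolic glutamine synthetase gene GLN1;1 (0.99), and those lower the glutamate synthase gene GLT1 (-0.56) and the asparagine synthetase gene ASN2 (-1.21).

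Flavonoid and anthocyanin genes were lower in 14 of 15 cases (median -0.46) but did not pass as a list (camera adjusted p = 0.0801). With 1 array left out the camera adjusted p ran from 4.82e-04 without ambient replicate 1 to 0.526 without ambient replicate 2, whose medians for this list lay -1.16 and 0.99 from the other ambient arrays. MYBL2, a repressor of the pathway, differed by 1.33 (SE 0.45), and the flavonol synthase gene FLS1 by -1.57 (SE 0.81), or -2.18 without low CO2 replicate 1, -2.36 without ambient replicate 1 and -0.93 without ambient replicate 2. Heat shock genes (median -0.18 over 9, camera adjusted p = 0.496) and jasmonate genes (median -0.21 over 16, camera adjusted p = 0.640) did not pass either. On ambient replicate 1 these lists lay 0.81 and 1.2 above the other ambient arrays. In these 3 lists limma passed 0 members over all genes and 0 adjusted over the list alone. Without low CO2 replicate 1 it called 1 flavonoid gene higher and 4 lower, 2 heat shock genes lower and 3 jasmonate genes lower over all genes, and the medians were -0.54, -0.32 and -0.34.

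Genes were also named after the data were seen, by the naming rule applied to the fit without low CO2 replicate 1. No overlap of the groups was still required on all 3 low CO2 arrays, so the direction on replicate 1 was fixed by the choice. By fold, the largest rises among genes with a symbol were in the glucosyltransferase gene UGT74E2 (256-fold), the cytochrome P450 gene CYP81D11 (151-fold), the glutathione transferase gene GSTU24 (72.1-fold), the glycosyltransferase gene UGT73C1 (54.1-fold), the glutathione transferase gene GSTU1 (52.7-fold), the transporter gene ABCB4 (48.2-fold), the sulfotransferase gene SOT12 (43.8-fold) and the transcription factor gene NAC032 (38.0-fold). Their limma adjusted p lay between 1.15e-05 and 1.45e-04. Over all 6 arrays the folds were, in the same order, 101, 39.2, 22.9, 20.4, 17.2, 19.4, 21.8 and 16.5. Without low CO2 replicate 3 they were 55.2, 17.9, 11.5, 11.6, 7.99, 10.8, 14.1 and 10.9. The ambient means of the first 6 lay between log2 3.51 and 4.51, near the filter's floor of log2 4, so neither the sizes nor the order of these folds is exact. On low CO2 replicate 1 itself the differences from the ambient mean were, in the same order, 15.5-fold, 2.64-fold, 2.31-fold, 2.88-fold, 1.82-fold, 3.15-fold, 5.40-fold and 3.09-fold. The largest falls were in the auxin-response gene IAA29 (log2 difference -2.76, SE 0.70), the expansin gene EXPA16 (-2.70, SE 0.33), the beta-glucosidase gene BGLU47 (-2.46, SE 0.31) and the HSP90 chaperone gene HSP81-2 (-2.22, SE 0.16). Over all 6 arrays IAA29 differed by -2.50, which became -1.76 without ambient replicate 1 and -3.16 without ambient replicate 2. EXPA16 lay at -2.38 from the ambient mean on low CO2 replicate 1, and HSP81-2 at -0.32.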

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

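The 0.10 threshold and the count of probe sets without overlap when an array is left out were chosen after seeing the data. At a 0.05 threshold limma called 0 probe sets, with 4236 at an unadjusted p under 0.05, and likewise 0 with no filter, a floor of log2 5, trend and robust settings, quantile normalization, median centring, the replicate block or Holm adjustment, with 4765, 3714, 4203, 4286, 4360 and 3223 at an unadjusted p under 0.05 for the first 6. Array weights gave 10371 calls, 4798 higher and 5573 lower, 909 and 554 of them at least 2-fold, and 10971 at an unadjusted p under 0.05. Those weights ran from 0.119 for low CO2 replicate 1 to 40.4 for low CO2 replicate 2, and the estimate did not converge, so the count rests mostly on 1 low CO2 array. At an adjusted p under 0.10 there were 95 calls, 57 higher and 38 lower, 44 and 18 of them at least 2-fold, as the looser threshold itself allows. Leaving out 1 array gave 0 to 5723 calls in all, 0 to 2722 higher, 0 to 3001 lower, 0 to 925 at least 2-fold higher and 0 to 571 at least 2-fold lower, the upper ends without low CO2 replicate 1 and 0 without each other array. Without that array 10307 probe sets, or 63.6%, had no overlap, where chance gives 20% for 2 against 3, and with it 4681. The 20% holds for an array left out blindly, not for the 1 that stood apart from its group. Simulated changes, placed on probe sets at random, were called at this number of arrays. Large real differences came with a wide spread, as in UGT74E2 and CYP81D11 with low CO2 SDs of 2.37 and 3.39. The simulation therefore cannot say what accounts for 0 calls.

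The replicate block left the count at 0 and the number of lists called at 11. Same-numbered arrays deviated from their group means with correlations of -0.19, 0.02 and -0.20, and by these deviations 0 of the 3 low CO2 arrays correlated best with the ambient array of their own number. By their values, all 3 correlated best with ambient replicate 1, at 0.986, 0.956 and 0.937. Since not every pair's deviations correlated above 0.1, the numbers were not taken to pair the samples. The deviations of the low CO2 arrays mostly reflect the distance of replicate 1 from the others, so these correlations do not exclude a pairing.

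The number of lists called was 11 or 12 under every filter, scaling, weighting and model setting and 10 to 11 with 1 array left out. It was 0 with an estimated correlation and 0 with fry's test of movement in 1 direction. With an estimated correlation the adjusted p was 0.497 for oxidative stress, aliphatic glucosinolates, circadian clock, senescence, touch and rapid stress and dividing cells, 0.507 for sugar starvation, abscisic acid, salicylate and cell wall expansion, and 0.585 for autophagy. With fry, which asks only whether a list's genes move one way, it was 0.0823 for oxidative stress, aliphatic glucosinolates and dividing cells, 0.0986 for circadian clock, senescence and touch and rapid stress, 0.101 for salicylate, 0.156 for abscisic acid and cell wall expansion, 0.200 for sugar starvation and 0.285 for autophagy. For both settings, the cause was not tested. Photorespiration and roots, not called by camera, also had an adjusted p of 0.0986 with fry. With array weights the adjusted p of cell wall expansion was 0.328, and the cause was not tested. With 1 array left out it ran from 0.00302 to 0.213 for cell wall expansion, highest without ambient replicate 1, and from 2.33e-06 to 0.0617 for salicylate, highest without low CO2 replicate 1. The other 9 lists called passed in all 6 omissions. Flavonoids, not called otherwise, passed at 0.0286 with no filter, 0.0408 with array weights and 4.82e-04 without ambient replicate 1, and reached 0.526 without ambient replicate 2 and 0.777 with an estimated correlation. Averaging several probe sets of a gene was not run, since each locus has 1. Of 125 named genes, 123 kept their direction after quantile normalization and 125 after median centring, and 95 passed limma without low CO2 replicate 1. The median difference over all probe sets stayed between -0.06 and -0.01 under every setting. Signal near the floor limits what can be read of dim genes.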

Other observations

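The pair correlation for shared replicate numbers, the comparison of arrays on the same ambient pair and the counts over other splits of the samples were chosen after the results were seen. The ribosomal protein list was drawn from the gene table's annotation after nucleolar genes and other genes of the ribosome, none of them in the list, were seen among the falls on these same arrays, and 2 genes that share a symbol with a listed gene were removed from it after a first run.

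Most listed cytosolic ribosomal protein genes were lower in low CO2. Over 34 genes the median log2 difference was -0.50, with 32 below the ambient mean, and the medians on low CO2 replicates 1, 2 and 3 were -0.21, -0.64 and -0.64. Since ribosomal genes move together and some had been seen to fall, these values describe the 34 listed genes on these arrays. They are no independent test of a fall of the class. Without low CO2 replicate 1, limma called 24 of these genes lower and 2 higher.

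Gene families of detoxification, chosen after the data were seen, moved unevenly. Over all 16210 probe sets, limma called 2722 higher and 3001 lower without low CO2 replicate 1. Of 20 tau-class glutathione transferase genes, 10 were higher and 5 lower without low CO2 replicate 1 by limma. Of 24 genes of the UGT71 to UGT79 glycosyltransferases, 10 were higher and 2 lower, and of 5 CYP81D genes 3 were higher and 0 lower, while 4 of the 5 lay above all ambient values on all 3 low CO2 arrays. The ambient arrays differed among themselves, with medians against the other ambient pair of 1.2, -0.70 and -0.57 for jasmonate genes and -1.16, 0.99 and 0.14 for flavonoid genes on replicates 1, 2 and 3.

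Low CO2 replicate 1 lay nearer to the ambient arrays than to the other low CO2 arrays. A batch shared by same-numbered arrays would move both replicate 1 arrays the same way. Their deviations correlated at -0.19, and on the first principal component they moved in opposite directions. That component separates low CO2 replicates 2 and 3 from the other arrays, and low CO2 replicate 1 deviates from its group mostly along it. The correlation therefore cannot decide on a batch. On the second component both replicate 1 arrays lay near -18.7, and the other arrays between 0.94 and 21.0. Ambient plants under a low CO2 label stay open: replicate 1 shared at least 105 differences of at least 2-fold with replicates 2 and 3 against a pair of ambient arrays, and the highest ambient array shared 108, but on another pair, so these 2 counts decide nothing. On the same pairs replicate 1 shared 105, 115 and 179 against 4, 21 and 108 for the remaining ambient array, which goes against this explanation without excluding it, since the ambient arrays themselves ran from 4 to 108. A mixture of responding and unresponding material cannot be told apart from a weaker response. Over 459 probe sets, a single share of 9.49% left an SD of 0.398 where replicates 2 and 3 differed by an SD of 0.355. The median share was 8.42% over risen and 22.8% over fallen probe sets. Their 10th to 90th percentiles overlapped, at 0.639% to 22.1% and -17.6% to 59.8%. Neither a mixture nor a uniformly weaker response would put replicate 1 further from ambient than both other low CO2 arrays. Among lists camera called, only salicylate and pathogen defence had such a median, 0.68 against 0.40 and 0.14. Ambient medians of this list ran from -0.29 to 0.24 against the other ambient pair, so the gap decides nothing. WRKY53 and KNOLLE also went further, but are single genes picked from many. A weaker or later biological response was not tested.

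Photorespiratory genes differed little in fold, with 0 of 27 at least 2-fold without low CO2 replicate 1. DiT1 came closest, at a log2 difference of -0.99. Compression of bright probe sets could hide part of a change. Outside the lists, the median absolute difference at log2 12 or more was 0.562 times that at log2 8 to 11, between the bounds set in advance, and abundant genes may also be steadier. Within the list the median absolute difference was 0.30 at log2 12 or more and 0.32 below, so the dimmer members differed as little. Probe sets outside the lists at log2 12 or more had a median of 0.22, with 6 of 123 at least 2-fold. The bright members therefore differed no less in their median than other bright probe sets. Neither explanation was excluded.

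The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real count of probe sets at an unadjusted p under 0.05 was 4236 and the highest other 3280, so 1 of 10 splits reached it. The count without overlap was 4681 against 3651, again 1 of 10. The number of lists called was 11, reached by 2 of the 10, with 11 the highest other and 2 the lowest. Camera with the preset correlation thus called lists under every grouping. The 0 calls by limma at an adjusted p under 0.05 were matched by all 10 splits. The split with 3280 placed low CO2 replicate 1 with ambient replicates 2 and 3, against the rest.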
